A study of Mus musculus with 6 samples.

How the data were processed

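Messenger RNA of MCEC cells was sequenced as tagmented cDNA libraries, per the labels' protocols, in 3 wild-type control and 3 Fat4 knockdown samples. The submitters' processing notes name FastQC 0.12.1, fastp 0.24.0, STAR 2.7.11, SAMtools 1.22.1, MultiQC 1.32 and the GRCm39 mouse genome. The read counter, its strand setting and the annotation release are not given in the sources used here. The deposited table has 78409 rows, of which 92 are spike-in sequences and 21909 carry no gene symbol. Its values are estimated counts per gene, as deposited, and 29.0% of the nonzero values are not whole (tolerance 1e-06). It also holds CPM values, which, as deposited, equal each count divided by the library's total. Counts split between features make genes that share reads with a near-identical copy, or overlap another gene, uncertain. Coordinates are those of the deposited table, spanning the first to the last exon base, counted from 1.

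Counts were rounded to whole numbers, since edgeR needs them, and spike-in rows were left out. A symbol shared by several rows stayed with the row of highest count. A first run left such symbols out of the lists, which took Ddit3 from the ATF4 list and Atp5po from the oxidative phosphorylation list. That handling, kept as a setting, calls 10 lists, the 2 more being ATF4 targets and TGF-beta and BMP targets. Genes were kept by filterByExpr, scaled by TMM, and tested with the quasi-likelihood test of edgeR 4.0.16 in R 4.3.3 (glmQLFit and glmQLFTest), control against knockdown without a block, at a Benjamini-Hochberg adjusted p under 0.05. The SE of a log2 fold change is its size divided by the square root of F. CPM means ± SD use TMM-scaled library sizes. Gene lists were tested with camera of limma 3.58.1 at a preset correlation of 0.01, adjusted over 32 lists with at least 3 tested members. None of the 8 called lists held with an estimated correlation. That correlation was 0.013 for the chaperone list, near the preset value, and -0.24 for the cardiomyocyte list. It was higher for the other called lists, up to 0.21 for the interstitial matrix list. Correlation between members therefore does not by itself account for the loss of every call. With an estimated correlation, camera also takes its degrees of freedom from the few libraries rather than from the genes, which by itself raises p-values. The adjusted p-values with an estimated correlation are thus no measure of correlation between members alone. Annotation terms were not analysed here. Values of 6 single measures were compared with two-sided exact permutation tests, which cannot go below p = 0.1 for 3 against 3.

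Before the data were examined, 11 primary and 22 secondary gene lists, the rule for named genes and the other settings to be tried were fixed. The rule took Fat4, then the 8 largest rises and 8 largest falls among changed genes with at least 10 CPM in the higher group, groups that did not overlap and a symbol that is not a predicted one. It then took up to 4 changed members of each primary list and up to 3 of secondary lists with 3 or more changed members or a call. Some genes that the rule takes are not reported here. These settings were RLE, upper-quartile and library-size scaling, leaving out mitochondrial and ribosomal protein genes, DESeq2 1.42.0, limma-voom, no filter, at least 10 CPM in 3 libraries, a replicate block, each library left out, and for lists an estimated correlation and fry. Settings chosen after seeing the data were a correction for GC content and exon length (smooth per-library trends fitted with mgcv 1.9-3 and used as offsets), rounding down, whole-number genes only, protein-coding genes only and leaving shared symbols out of the lists. GC percent came from a GRCm38 annotation matched by gene identifier.

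The workflow was tested on simulated counts for knockdown against control over 13219 genes, 200 of them changed. It called 33 of 50 genes changed 1.3-fold, 47 of 50 changed 1.5-fold, and 50 of 50 at both 2-fold and 3-fold, with 12 of 192 calls false. The changed genes were drawn from those above 10 CPM, and every gene had the same dispersion. No GC or length trend and no displaced library was simulated in this step. These shares therefore do not cover low genes such as Fat4, or the trends and displaced control library of the real data. The biological coefficient of variation of the real libraries was 6.31%. A count of 0 allows 3 counts, which is 0.25 to 0.29 CPM across libraries, and such limits cover counting error only. Figures were drawn with matplotlib.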

Results

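RNA sequencing libraries were compared from MCEC, an immortalised line derived from mouse cardiac endothelium, in 2 groups of 3. One group was wild type and the other carried a short hairpin RNA against Fat4, an atypical cadherin that binds Dachsous proteins and takes part in planar cell polarity and Hippo signalling. Whether the control libraries carried a non-targeting hairpin, and whether the 3 libraries of a group came from separate cultures, is not given in the sources used here, so p-values measure the spread between these libraries, which may be technical. The total count was 10305810, 11122039 and 11870091 in the control libraries and 11538010, 10509069 and 11092763 in the knockdown libraries. Mitochondrially encoded genes took 4.96% ± 0.13 of counts in control and 4.62% ± 0.20 in knockdown libraries (SD, n = 3, two-sided exact permutation test p = 0.2). Genes with ribosomal protein symbols, a set taken by symbol alone, took 12.4% ± 0.65 and 14.2% ± 0.38 (SD, n = 3, two-sided exact permutation test p = 0.1, the smallest that 3 against 3 allows). No pair of libraries within a group agreed within sampling noise, so all 6 were kept. The comparison addresses how lowering Fat4 alters expression in this line, a question the study sets in the context of tumour vessel growth and tumour immunity. Of 31 endothelial identity genes, 23 lay under 1 CPM in both groups.

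Fat4 itself (ENSMUSG00000046743, GRCm39 chromosome 3, exons spanning 38941089 to 39066134) was scarce in both groups and lower in the knockdown. Its deposited counts were 10, 22 and 31.5 in control replicates 1, 2 and 3 and 8.5, 10 and 9 in the knockdown libraries. Normalised expression was 1.83 ± 0.80 CPM in control and 0.85 ± 0.11 CPM in knockdown libraries (SD, n = 3), a log2 fold change of -1.17 (SE 0.35, edgeR quasi-likelihood adjusted p = 0.033). Control replicate 1, at 0.97 CPM, lay within the knockdown range, and a two-sided exact permutation test of the 6 values gave p = 0.2 (n = 3). The call was lost in 5 of the 6 fits that left out one library, where the adjusted p reached 0.205 without control replicate 3, and it held without control replicate 1 (log2 fold change -1.44, edgeR adjusted p = 0.0021). Limma-voom gave an adjusted p of 0.058, and the fit corrected for GC content and length gave 0.063.

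**Figure D1:**
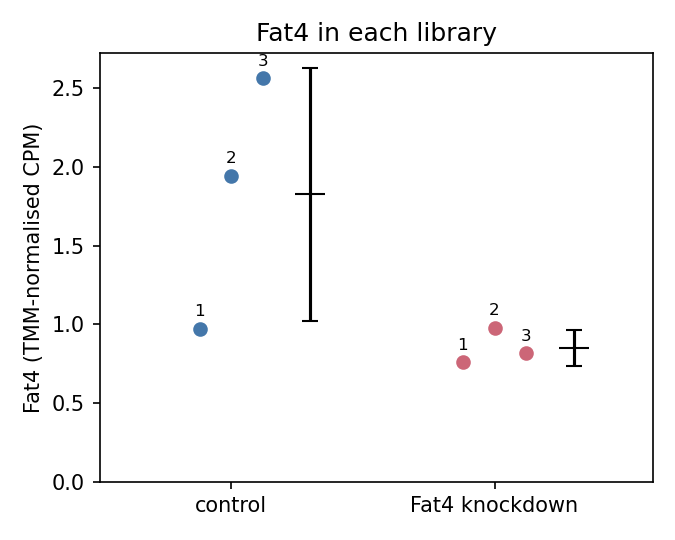
Fat4 expression in each library as TMM-normalised CPM (vertical axis), with points numbered by replicate and the group mean ± SD (n = 3) beside them. Control replicate 1 sits at 0.97 CPM, beside the knockdown libraries, and control replicate 3 at 2.56 CPM.

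Among 13372 genes tested, 2324 changed between knockdown and control, 1195 upward and 1129 downward (edgeR quasi-likelihood test, Benjamini-Hochberg adjusted p under 0.05). Most changes were small: the median fold of the changed genes was 1.26, and 86.6% changed by less than 1.5-fold. A change of at least 2-fold was seen for 73 genes, 26 higher and 47 lower. Over all tested genes, the 2 groups did not overlap in 34.9%, which chance gives for 10% of genes with 3 against 3. Scaling by library size alone gave 2593 changed genes, of which 32.9% were higher against 51.4% under TMM. DESeq2 called 1443 genes, and fits without one library called from 1029 (without control replicate 2) to 3077 (without control replicate 1). The count also fell to 1226 without control replicate 3, to 1216 without knockdown replicate 1 and to 1165 without knockdown replicate 2. Without control replicate 1, 154 genes changed at least 2-fold.

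The largest rises among changed genes reaching 10 CPM whose groups did not overlap were of Wincr1, a long noncoding RNA, and Tmem171, a membrane protein gene. Wincr1 (ENSMUSG00000085183, chromosome 4, 88964654 to 89002905) went from 9.47 ± 2.24 to 20.5 ± 1.03 CPM (SD, n = 3, log2 fold change 1.13, SE 0.13, edgeR adjusted p = 5.23e-05). Tmem171 went from 6.62 ± 0.24 to 13.6 ± 0.80 CPM (SD, n = 3, log2 fold change 1.04). The atrial myosin light chain gene Myl7 rose by a log2 fold change of 0.96, the granzyme B inhibitor gene Serpinb9 by 0.89, the phospholipase gene Plaat3 by 0.82, the osteopontin gene Spp1 by 0.76, the centromere protein gene Itgb3bp by 0.74 and the endothelial surface gene Ecscr by 0.72. Their edgeR adjusted p-values ranged from 0.000123 for Plaat3 to 0.00432 for Serpinb9.

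The largest falls within the same limits were of Lncucc1, a long noncoding RNA, and Ptp4a3, which encodes a phosphatase. Lncucc1 (ENSMUSG00000086311, chromosome 11, 35240896 to 35241612) went from 10.6 ± 0.90 to 4.57 ± 1.40 CPM (SD, n = 3, log2 fold change -1.23, SE 0.17, edgeR adjusted p = 0.000278). Ptp4a3 went from 10.9 ± 1.79 to 4.82 ± 0.62 CPM (SD, n = 3, log2 fold change -1.18). The ephrin receptor gene Ephb2 had a log2 fold change of -1.04, the lipopolysaccharide binding protein gene Lbp -0.91, the hyaluronan-degrading gene Cemip -0.86, Fam180a -0.86, the Unc5-binding membrane protein gene Flrt1 -0.82 and the adenylate cyclase gene Adcy1 -0.80. Cemip had the smallest edgeR adjusted p of these, 9.59e-06, with 40.9 ± 1.06 against 22.5 ± 0.69 CPM (SD, n = 3). The call of each of these 16 genes held in every fit run on it.

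**Figure D2:**
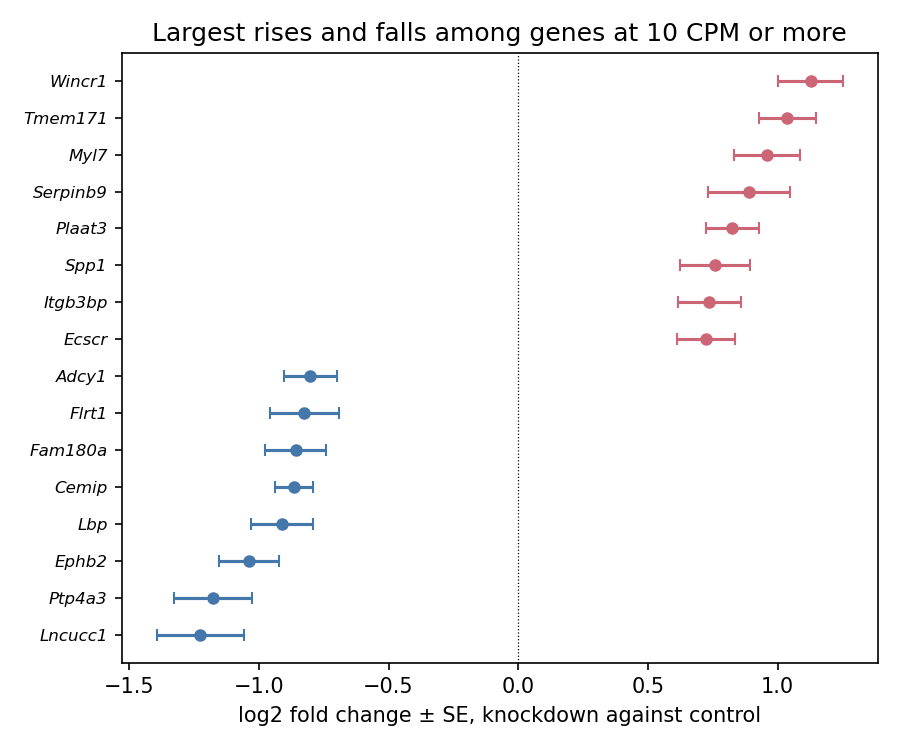
Log2 fold change of knockdown against control (horizontal axis) with its SE for the 8 largest rises and 8 largest falls among changed genes reaching 10 CPM whose groups did not overlap. Values run from -1.23 for Lncucc1 to 1.13 for Wincr1.

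Genes for angiogenic factors, their receptors and tip cells fell as a group. Of 24 members tested, 13 fell and 1 rose, both over all genes and adjusted over the list alone (median log2 fold change -0.29, camera adjusted p = 0.000166, and adjusted p = 0.383 with an estimated correlation). The metalloproteinase inhibitor gene Timp3 went from 379 ± 8.75 to 239 ± 10.8 CPM (SD, n = 3, log2 fold change -0.67, edgeR adjusted p = 9.59e-06). Adamts1 (-0.70), Thbs1 (-0.68) and Vegfa (-0.41), of which Adamts1 and Thbs1 are known inhibitors and Vegfa the main promoter of vessel growth, fell as well. GC and length correction left 10 lower and 1 higher. The list held falling members known to promote and falling members known to restrain vessel growth. Of 14 mesothelial genes, listed after the changed genes had been seen, 9 fell and 0 rose. The one member of the angiogenic list that rose was Flt4, a receptor for lymphatic growth factors, with a log2 fold change of 0.46. Its call was lost without control replicate 2, control replicate 3 or knockdown replicate 1 and by DESeq2.

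The lists closest to Fat4 signalling moved downward by small amounts. Of 22 YAP and TAZ target genes, 7 fell and 1 rose, with the same counts adjusted over the list alone (median log2 fold change -0.09, camera adjusted p = 0.024, and adjusted p = 0.482 with an estimated correlation). Igfbp3 (log2 fold change -0.79), Ccdc80 (-0.53) and Tgfb2 (-0.52) fell, while Ankrd1, often used as a readout of YAP activity, rose from 147 ± 2.29 to 233 ± 13.2 CPM (SD, n = 3, log2 fold change 0.66, edgeR adjusted p = 1.01e-05). Of 31 tested genes of the Fat and Dachsous, Hippo core and planar polarity list, 9 fell and 0 rose, and 10 fell and 2 rose adjusted over the list alone (median log2 fold change -0.13, camera adjusted p = 0.024, and adjusted p = 0.482 with an estimated correlation). Wwc1 (-0.41) and Wwc2 (-0.39), which encode upstream Hippo scaffolds, Amotl2 (-0.30) and Tead3 (-0.30) were among those that fell. Correction for GC content and length ended both list calls, with camera adjusted p-values of 0.258 and 0.425, medians of -0.03 and -0.06, and 1 higher and 5 lower against 2 higher and 4 lower members, and also ended the calls of Amotl2 and Tead3. The call of Tead3 was lost without control replicate 2 or knockdown replicate 2 as well. The Fat and Hippo call was also lost without control replicate 3 (camera adjusted p = 0.0933) and without knockdown replicate 1 (0.0786).

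Most core endothelial genes were near or below detection in both groups. Only 8 of 31 endothelial identity genes could be tested, and 10 had no count in any library, among them Vwf, Erg, Cldn5 and Tie1, where a count of 0 allows up to 0.25 to 0.29 CPM per library (3 counts, counting error only). Cdh5 had 1 count per group, and Pecam1 was at 0.52 ± 0.24 and 0.54 ± 0.41 CPM (SD, n = 3). Ecscr rose, and Flt1 (log2 fold change -0.59) and Eng (-0.42) fell, with the same counts adjusted over the list alone. The call of Eng was lost in 4 of the 6 fits without one library and after GC and length correction, and that of Flt1 by DESeq2. Cd34, at 52.5 ± 3.80 and 53.1 ± 1.12 CPM (SD, n = 3), did not pass the test. The list was not called (camera adjusted p = 0.796). Of 7 tested lymphatic endothelial genes, 3 rose and 2 fell, as many adjusted over the list alone (camera adjusted p = 0.692), with Sema3a (-0.59) and Sema3d (-0.51) lower. Of 11 Notch pathway genes, Lfng, Maml2 and Notch1 fell and Rbpj rose, over all genes and over the list alone (camera adjusted p = 0.505), and each of these calls was lost in at least one fit without a library. Corrected for GC content and length, 1 endothelial identity gene rose and 1 fell, 2 lymphatic genes rose and 2 fell, and 1 Notch gene rose and 2 fell.

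Chemokine and cytokine genes moved both ways. Of 20 tested, 4 rose and 5 fell, and 5 rose and 7 fell adjusted over the list alone (camera adjusted p = 0.692, median log2 fold change -0.04, mean 0.03). The monocyte attractant gene Ccl2 went from 47.1 ± 2.05 to 60.0 ± 2.46 CPM (SD, n = 3, log2 fold change 0.35, edgeR adjusted p = 0.0023), a call lost after GC and length correction, and the T cell attractant gene Cxcl10 rose from 2.20 ± 0.45 to 4.24 ± 0.50 CPM (log2 fold change 0.94). Cxcl12 (log2 fold change -0.57) and Tgfb2 (-0.52) fell. The list had 3 higher and 4 lower after GC and length correction, with a median of -0.16 (camera adjusted p = 0.231). Of 13 leukocyte adhesion genes, 3 fell and 0 rose, with the same counts adjusted over the list alone: Vcam1 (-0.36), Alcam (-0.55) and F11r (-0.21). That list missed the threshold (camera adjusted p = 0.0534), and the calls of Alcam and F11r were lost in 4 of the 6 fits without one library. GC and length correction left 3 lower and 0 higher in it (camera adjusted p = 0.0703).

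Antigen presentation, interferon and NF-kappaB genes showed no shared shift past the threshold. Of 16 antigen presentation genes, Psmb10 (log2 fold change 0.31), Psme1 (0.30), B2m (0.24) and H2-M3 (0.42) rose and Calr (-0.28) fell, with the same counts adjusted over the list alone (camera adjusted p = 0.505). After GC and length correction B2m turned to -0.07, and its call was also lost without control replicate 2. The call of H2-M3 was lost in 5 of the 6 fits without one library, that of Psme1 in 3, and that of Calr without knockdown replicate 2. Of 21 interferon-stimulated genes only Isg15 rose, over all genes and adjusted over the list alone (log2 fold change 0.83, edgeR adjusted p = 0.0191, camera adjusted p = 0.261 for the list), and its call was lost in 4 of the 6 fits without one library. Of 18 NF-kappaB genes 3 rose and 3 fell, and 4 rose and 4 fell adjusted over the list alone (camera adjusted p = 0.988), with the inhibitor gene Nfkbia at 0.32, Bcl3 at -0.44 and Tnfaip2 at -0.40. Of 12 immune checkpoint and co-stimulatory ligand genes only Nectin2 fell (log2 fold change -0.24, camera adjusted p = 0.692 for the list), over all genes and adjusted over the list alone, a call lost without control replicate 2 or knockdown replicate 2 and after GC and length correction. The corrected counts were 4 higher and 3 lower for antigen presentation, 0 and 0 for interferon-stimulated genes, and 4 and 3 for NF-kappaB genes.

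Interstitial matrix genes and endoplasmic reticulum chaperone genes each fell as a group. In the same libraries 9 of 14 mesothelial genes, listed after the changed genes had been seen and not tested as a list, fell and 0 rose (median log2 fold change -0.33). Of 24 matrix genes 12 fell and 0 rose, and 13 fell and 1 rose adjusted over the list alone (median log2 fold change -0.24, camera adjusted p = 2.2e-05, and adjusted p = 0.444 with an estimated correlation). The fibrillar collagen gene Col3a1 went from 369.9 ± 14.03 to 238 ± 12.2 CPM (SD, n = 3, log2 fold change -0.64, edgeR adjusted p = 1.17e-05), and Bgn (-0.57) and Col6a2 (-0.59) fell as well. Of 20 chaperone genes 10 fell and 0 rose, and 13 fell adjusted over the list alone (median log2 fold change -0.21, camera adjusted p = 2.2e-05, and adjusted p = 0.267 with an estimated correlation). Hspa5, the main lumenal chaperone gene, went from 994 ± 2.47 to 792 ± 33.5 CPM (SD, n = 3, log2 fold change -0.33), with Hsp90b1 (-0.34) and Pdia6 (-0.35) also lower. Of 23 cholesterol synthesis genes 5 fell and 0 rose, with the same counts adjusted over the list alone (median log2 fold change -0.09, camera adjusted p = 0.024, and adjusted p = 0.437 with an estimated correlation). Hmgcs1, an early enzyme gene of the pathway, was among those that fell (log2 fold change -0.38). Under GC and length correction 10 matrix, 13 chaperone and 4 cholesterol synthesis genes fell and 0 rose in each list. Without knockdown replicate 2 the cholesterol call was lost (camera adjusted p = 0.0545).

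Nuclear genes for oxidative phosphorylation rose together by small amounts. Of 38 tested, 17 rose and 0 fell, and 18 rose and 1 fell adjusted over the list alone (median log2 fold change 0.15, camera adjusted p = 5.17e-05, and adjusted p = 0.444 with an estimated correlation). Cox6c went from 266 ± 26.5 to 335 ± 9.25 CPM (SD, n = 3, log2 fold change 0.33), and Ndufa2 (0.31) and Atp5f1c (0.26) rose as well. After GC and length correction 7 rose and 1 fell, the median was 0.06 and the camera adjusted p 0.0485, and the call of Ndufa2 was lost. Of 16 cardiomyocyte marker genes, 3 could be tested and 2 rose, as many adjusted over the list alone (camera adjusted p = 0.0134, and adjusted p = 0.383 with an estimated correlation). They were Myl7 and the natriuretic peptide gene Nppb, which went from 0.91 ± 0.05 to 2.49 ± 0.24 CPM (SD, n = 3, log2 fold change 1.44, edgeR adjusted p = 0.0016). Nppb was scarce, with 9 to 31 counts a library, and DESeq2 gave it no adjusted p. The filter at 10 CPM left too few cardiomyocyte markers for a list test.

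**Figure D3:**
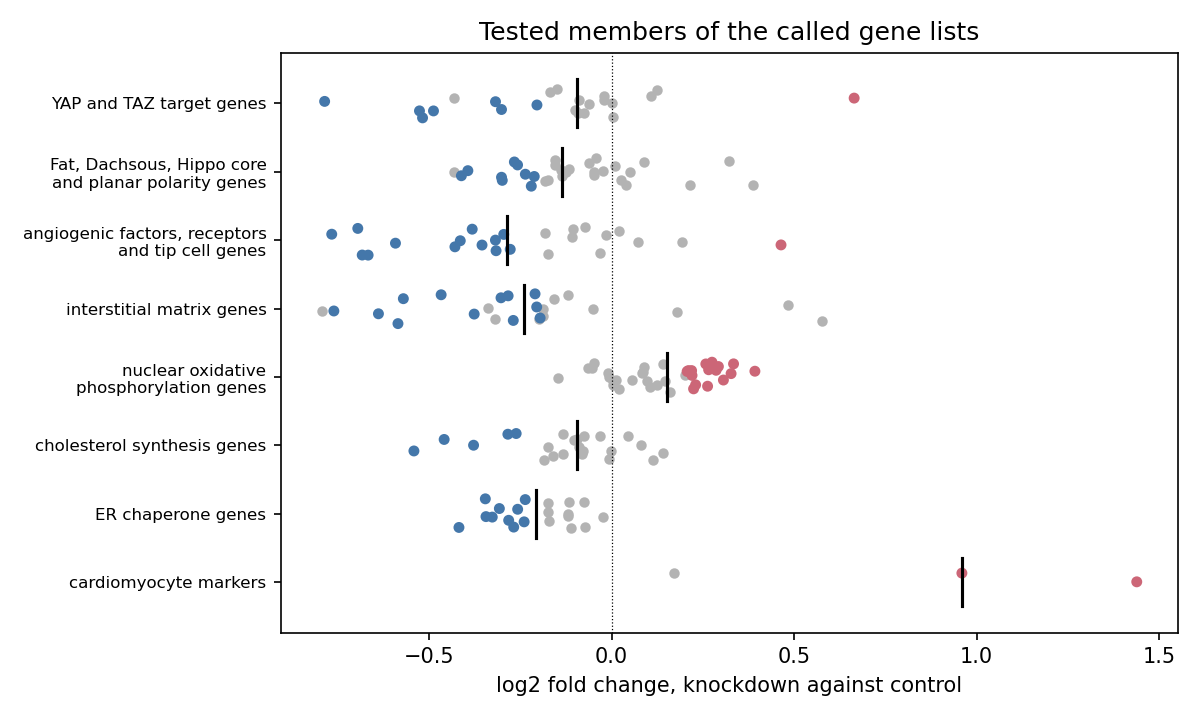
Log2 fold change of knockdown against control (horizontal axis) of each tested member of the 8 lists with a camera adjusted p under 0.05; red points rose and blue points fell at edgeR adjusted p under 0.05, grey points did not pass, and black bars are medians. Medians run from -0.29 for the angiogenic list to 0.96 for the 3 cardiomyocyte markers.

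Other fixed lists were not called by camera. TGF-beta and BMP target genes lay at the threshold (6 of 18 fell, 7 adjusted over the list alone, 0 rose, camera adjusted p = 0.0501), with Smad6 (log2 fold change -0.62), Bmp4 (-0.42) and Atoh8 (-0.32) lower. That list passed with library-size scaling (0.0329), a replicate block (0.0494), without control replicate 2 (0.0443) and without knockdown replicate 2 (0.0370). It reached 0.0949 without control replicate 3 and 0.167 after GC and length correction, with 1 higher and 3 lower. Of 24 ATF4 target genes, 6 fell and 1 rose, and 11 fell and 2 rose adjusted over the list alone (camera adjusted p = 0.0534), with Atf5 (-0.35) and Trib3 (-0.52) lower and Ddit3 (0.40) higher. The ATF4 list passed without knockdown replicate 1 (0.0379) and reached 0.156 without knockdown replicate 2, and 0.167 after GC and length correction, with 1 higher and 4 lower. With symbols on more than 1 row left out of the lists, here Ddit3, the ATF4 list gave a camera adjusted p of 0.0214 and the TGF-beta and BMP list 0.0451. Of 22 immediate-early genes 5 rose and 0 fell, and 8 rose and 2 fell adjusted over the list alone (camera adjusted p = 0.0534), with Fosl1 (0.38), Dusp6 (0.39) and Klf10 (0.28) higher. That list passed after GC and length correction, with 7 higher (camera adjusted p = 0.00404, median 0.13), without control replicate 3 (0.0353) and without knockdown replicate 2 (0.0472), and reached 0.216 without control replicate 1. Of 21 p53 target genes 6 rose and 0 fell, and 6 rose and 1 fell adjusted over the list alone (camera adjusted p = 0.132). Plk2 (0.27), Ccng1 (0.28) and Perp (1.12) were higher. Perp was scarce, at 0.56 ± 0.03 CPM in control and 1.23 ± 0.20 CPM in knockdown libraries (SD, n = 3), and DESeq2 gave it no adjusted p. The corrected counts for p53 targets were 3 higher and 0 lower, with the median going from 0.14 to 0.05 (camera adjusted p = 0.0701). Of 20 glycolysis genes 3 fell, as many adjusted over the list alone (camera adjusted p = 0.0534): Gpi1 (-0.22), Pkm (-0.19) and Pfkp (-0.24). After GC and length correction 0 glycolysis genes fell and 1 rose, with the median going from -0.10 to -0.04 (camera adjusted p = 0.751), while library-size scaling gave 0.0346. Hypoxia response genes went both ways (5 of 22 rose and 4 fell, as many adjusted over the list alone, camera adjusted p = 0.796), as did NRF2 target genes (2 of 20 rose and 4 fell, 2 and 5 adjusted over the list alone, camera adjusted p = 0.261), with Hilpda (0.44) and Prdx1 (0.27) higher and Tkt (-0.44) lower. The corrected counts were 2 higher and 3 lower for hypoxia and 0 and 4 for NRF2. The calls of Atoh8, Ddit3, Dusp6, Klf10, Ccng1, Perp, Gpi1, Pkm, Pfkp and Prdx1 were each lost in at least 1 fit without one library.

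Proliferation genes changed little as groups. Of 34 S phase genes 6 rose and 2 fell, and 7 and 2 adjusted over the list alone (camera adjusted p = 0.514), with Pcna at a log2 fold change of 0.42, Prim1 at 0.44 and Cdt1 at -0.29. Of 36 G2 and M phase genes 3 rose and 2 fell, and 2 and 2 adjusted over the list alone (camera adjusted p = 0.813), with Cenpa at 0.26 and Bub1b at -0.23, a call lost in 4 of the 6 fits without one library. Corrected for GC content and length, 5 S phase genes rose and 1 fell, and 3 G2 and M phase genes rose and 3 fell. Of 17 junction genes 1 rose and 3 fell, as many adjusted over the list alone (camera adjusted p = 0.256), with Jup at -0.28, and 0 rose and 1 fell after GC and length correction. Basement membrane genes had 2 of 13 lower, 1 adjusted over the list alone (camera adjusted p = 0.344, median -0.13). After GC and length correction 4 of them were higher and 1 lower (camera adjusted p = 0.167, median 0.06), so their direction depends on that step. Endothelial-to-mesenchymal transition genes had 1 of 17 higher and 1 lower, as many adjusted over the list alone (camera adjusted p = 0.951, median -0.01, mean 0.03). No Wnt and beta-catenin target gene passed among 7 tested (camera adjusted p = 0.601). Among markers of other cell types, 1 of 5 fibroblast and mural genes rose and 1 fell, 2 and 2 adjusted over the list alone (camera adjusted p = 0.692), 1 of 6 epithelial genes fell, as many adjusted over the list alone (camera adjusted p = 0.692), and neither of 2 tested leukocyte genes passed.

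By chromosome, median log2 fold changes were all small. For 10 of 20 chromosomes the median differed from that of random gene sets of the same size and similar mean expression (10000 sets, Benjamini-Hochberg adjusted p under 0.05), 5 above and 5 below it. The medians ranged from -0.04 for chromosome 15 (524 genes, random-set adjusted p = 0.010) to 0.05 for the X chromosome (425 genes, random-set adjusted p = 0.0040). Random sets treat genes as independent, so these p-values do not measure the spread between libraries. The sets were not matched on GC content or exon length, with which fold changes fell.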

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

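The correction for GC content and length, whole-number genes, protein-coding genes and leaving shared symbols out of lists were chosen after the data were seen. The count of changed genes was 1443 by DESeq2, with 32 at least 2-fold, 883 among whole-number genes, and 1029 to 3077 with one library left out. The count of genes changed at least 2-fold was 139 without a filter, 9 at 10 CPM in 3 libraries, 45 among protein-coding genes, and 52 to 154 with one library left out. The filters and subsets test other genes by construction; for DESeq2 the cause was not tested. GC and length correction left 1598 changed genes, 1252 of them shared with the main result in the same direction. Same-numbered replicates did not deviate together (correlations -0.21, -0.20 and 0.18), and a replicate block gave 2001 changed genes, 66 at least 2-fold, and a log2 fold change of -1.12 for Fat4. Not every library correlated best with its own number.

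Fat4 had a log2 fold change of -1.04 by limma-voom and -0.997 after GC and length correction, neither past the threshold, and -1.44 to -0.82 with one library left out. DESeq2 gave it no adjusted p, and the filter at 10 CPM left it out. B2m reversed to -0.0691 after GC and length correction; the cause was not tested further. Of 93 named entries, 19 others lost their call under that correction, 13 of 91 under DESeq2, and 5 to 26 when one library was left out.

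List calls in camera adjusted p: with an estimated correlation, 0.482 for YAP and TAZ targets, 0.482 for the Fat and Hippo list and 0.383 for the angiogenic list; after GC and length correction, 0.258 for YAP and TAZ targets and 0.425 for the Fat and Hippo list. Fry, which tests whether members move one way, gave 0.0538 for YAP and TAZ targets and 0.0538 for the Fat and Hippo list, and passed 8 lists that camera did not: Notch (0.0302), leukocyte adhesion (0.0209), TGF-beta and BMP targets (0.0209), p53 targets (0.0222), glycolysis (0.0375), ATF4 targets (0.0375), NRF2 targets (0.0375) and immediate-early genes (0.0403). It reversed the lymphatic list to lower at 0.0174; the cause was not tested. Leukocyte adhesion passed under library-size scaling (0.0397) and the replicate block (0.0364). With one library left out the Fat and Hippo list ranged from 0.00949 to 0.0933 and leukocyte adhesion from 0.0255 to 0.121. Depth limits low genes such as Fat4, with 8.5 to 31.5 counts a library.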

Other observations

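The lists in this part were written after the changed genes had been seen, and the tests of GC content and length on gene lists were chosen only after their results were seen. Genes with ribosomal protein symbols were higher in the knockdown: of 97 tested, 55 rose and 2 fell (median log2 fold change 0.21, camera of limma adjusted over the 4 lists of this part, adjusted p = 7.49e-15, and adjusted p = 0.208 with an estimated correlation). They were taken by symbol alone (protein-coding, Rpl or Rps plus a digit, Rplp or Rpsa). That pattern also takes genes that encode no ribosomal protein, such as kinase genes whose symbols start alike. After correction for GC content and length 39 rose and 0 fell, with a median of 0.14 (camera adjusted p = 2.45e-11). Ribosomal protein genes have many processed pseudogenes, and 93 of the 97 genes had fractional counts, so their values are uncertain. The median of the 97 was 0.15 with library-size scaling. Host genes of small nucleolar RNAs rose as well. Without 3 members whose values had been seen, 7 of 14 rose and 0 fell (median 0.26, camera adjusted p = 2.02e-05, adjusted p = 0.208 with an estimated correlation, and adjusted p = 5.21e-05 after GC and length correction). Snhg1 went from 268 ± 38.2 to 415 ± 9.96 CPM and Gas5 from 282 ± 40.9 to 403 ± 7.60 CPM (SD, n = 3). Ribosome biogenesis genes showed no such shift before correction (3 of 39 rose and 1 fell, camera adjusted p = 0.396, median -0.05 over 40 genes with library-size scaling against 0.01) and gave an adjusted p = 0.0411 after it, so whether they shift is open.

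Axon guidance ligands and receptors were lower. Of 47 tested, 22 fell and 0 rose. Without 12 members that had been seen or belong to another list, 14 of 35 fell and 0 rose (median log2 fold change -0.24, camera adjusted p = 8.33e-05, adjusted p = 0.208 with an estimated correlation). One seen member, Nrp2, and the members of other lists were added to those left out after a first run of the test. After GC and length correction 9 fell and 1 rose (median -0.14, camera adjusted p = 0.011). Efnb1 went from 67.7 ± 2.88 to 40.9 ± 1.75 CPM, Slit3 from 48.4 ± 1.87 to 29.2 ± 1.56 CPM and Plxna4 from 43.0 ± 6.24 to 27.4 ± 0.74 CPM (SD, n = 3). Outside the rule for named genes, and chosen after its values were seen, the platelet chemokine gene Ppbp rose from 1.85 ± 0.33 to 8.15 ± 1.06 CPM (SD, n = 3, log2 fold change 2.13, edgeR adjusted p = 9.59e-06), and the metallothionein gene Mt1 from 194 ± 9.02 to 306 ± 8.06 CPM.

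Fold changes fell with GC content (Spearman rho -0.23) and exon length (-0.25) across 12787 genes, which are not independent replicates. Technical trends of this kind may account for part of the list calls. Removing them kept the calls, and most of the median, of the chaperone (camera adjusted p = 2.47e-07), angiogenic (0.00163), matrix (0.00404), cholesterol (0.0253) and cardiomyocyte lists (0.0117), which argues against such trends as their whole cause. It ended those of YAP and TAZ targets (0.258; median -0.09 to -0.03, interquartile range 0.29 to 0.33) and the Fat and Hippo list (0.425; -0.13 to -0.06, 0.22 to 0.17), since the medians lost more than they kept, and left oxidative phosphorylation at 0.0485 with its median down from 0.16 to 0.06, which decides nothing; immediate-early genes, not called before, passed after it (0.00404). Whether the trend is technical cannot be told apart from the groups: their mean GC slopes differ by 0.0947 log2 units per 10 percentage points, but the nearest libraries of the groups by 0.029, less than the range of 0.0717 within a group. An effect of the knockdown stays open.

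Control replicate 1 lay towards the knockdown. It was placed on 3043 genes called without it that also passed the filter on all 6 libraries. It stood at 0.581 of the way from the knockdown mean (0) to the other controls (1). Control replicates 2 and 3, measured likewise, stood at 0.921 and 1.12, but their reference includes control replicate 1. On their own axes, knockdown replicates 1, 2 and 3 stood at 0.897, 0.919 and 0.754. After GC and length correction control replicate 1 stood at 0.632, against 0.901 and 0.994 for control replicates 2 and 3. This argues against those trends as the cause. Knockdown cells or RNA mixed into control replicate 1 may also account for its position. The prediction set beforehand was that mixing gives like fractions for rising and falling genes. These differed by -0.145 (0.511 against 0.656, bootstrap intervals over genes not overlapping). Positions were taken on log2 values, where mixing RNA in fixed amounts need not give like fractions, so this difference cannot decide. Control replicate 3 differed by 0.242 the other way, but its axis includes control replicate 1, so that is no separate measure of spread. Mixing stays open, as does a culture difference.

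Core endothelial genes were at or near 0 in every library. Of 31 endothelial identity genes 10 had no count. Of all 31, 74.2% lay under 1 CPM in both groups. Of the 21 with a count 61.9% did, against 56.3% of all genes with a count. That wider set includes noncoding genes, and 17118 of its 30490 members were not tested. The share was 75% of 8 cardiomyocyte and 80% of 10 leukocyte markers with a count, and 0% of S phase, chaperone and oxidative phosphorylation genes. A count of 0 allows up to 0.25 to 0.29 CPM per library (3 counts, counting error only). This argues against depth hiding expression above that limit in the 10 genes with no count. Expression below it stays open. A candidate explanation of the low endothelial genes is that the cells have a mesothelial-like profile. Of 20 mesothelial genes listed after the changed genes had been seen, 14 were neither recorded as seen nor members of another list. Of these 14, 92.9% reached 10 CPM, against 8838 of all 30490 genes with a count. They were led by Upk1b at 667 ± 5.12 and Upk3b at 563 ± 34.8 CPM in control libraries (SD, n = 3), with Msln at 114 ± 4.02 and Wt1 at 98.7 ± 4.38 CPM. Of all 20 genes listed, 16 reached 10 CPM, and the members left out include the low Krt7, Krt8 and Krt18. Since 9 of the 14 are themselves changed genes, their share is no independent test. Among the listed keratin genes, Krt8 (1.10 ± 0.25 CPM in control libraries), Krt18 (1.14 ± 0.38) and Krt7 (3.05 ± 0.43), expected in mesothelium, were low (SD, n = 3). Krt19 and Krt14, at 112 ± 0.67 and 282 ± 8.20 CPM in control libraries, were not (SD, n = 3). Of these 14 genes 9 fell in the knockdown and 0 rose (8 and 0 after GC and length correction), Upk3b to 420.2 ± 12.7 CPM. Of the 20 genes listed, 5 belong to another list, and some, such as Cav1 and C3, are expressed by other cell types too, and altered expression in a cultured line was not tested.

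The 6 libraries allow 10 splits of 3 against 3, too few for a share under 0.05. The real split gave the highest count (1 of 10) for each measure: 2324 changed genes and 73 changed at least 2-fold, against 0 for the highest other split by edgeR in both, and 8 called lists against 5. At an unadjusted p under 0.05 the real split had 4171 genes and the highest other split 950. Each other split puts control and knockdown libraries in both groups. Any difference between control and knockdown then adds to the spread within groups and lowers the counts. The other splits are therefore no measure of the count that chance alone would give.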
